A study of Escherichia coli
Pseudomonas phage PP7 and Escherichia coli with 40 samples.

How the data were processed

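The data are SHAPE-seq libraries of the PP7-wt and PP7-USs reporter transcripts in E. coli, in vivo and in vitro, and of 5S rRNA. Per the file headers, the deposited 5S rRNA table holds counts of read ends per nucleotide, and the 4 deposited tables of the constructs hold read-end counts of the same kind, checked to be whole and not negative. Per the submitters' processing notes the authors aligned reads with Bowtie2, whose version is not stated. Reads were 101 nucleotides long for the constructs in vivo and 51 for the constructs in vitro and for 5S rRNA, per the labels. The tables do not say whether an end was assigned to the modified nucleotide or to its neighbour, so every position may be off by 1 from the modified base. The 5 tables hold 28 columns for 40 samples, since an in vitro or 5S group of 2 technical replicates has 1 column. Whether that column holds 1 replicate or the sum of both is not stated. The constructs have 241 and 239 nucleotides in the tables, of which the last 22 carry no counts, and 5S rRNA has 120, of which 101 carry counts.

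The stop rate of a position is its number of ends divided by the reads that reached it, which are its own ends and all ends further 5', full-length cDNA included. Positions needed a mean of at least 10 ends and at least 100 reads in every library, and the full-length position was not tested. edgeR 4.0.16 (quasi-likelihood F test, limma 3.58.1, R 4.3.3) was fitted per construct to the 8 in vivo libraries in 4 groups, with the log of the reads that reached a position as offset. The contrasts were NAI against unmodified without and with induction, their interaction, and induction in unmodified libraries. The same contrasts were compared between constructs in a fit of all 16 libraries over 217 positions with matching bases. P values were adjusted by Benjamini-Hochberg over the positions of a contrast, at a threshold of 0.05. Of 9 regions, fixed from the hairpin sequence, those with at least 3 tested positions were tested with fry, for change in 1 direction and in either direction. The fry tests ask whether a region's positions change and do not compare regions. In vitro and 5S groups have 1 library, so stop rates are given with exact Clopper-Pearson 95% intervals and no test. Permutation tests of correlations were two-sided with 100000 permutations. The in vitro summaries and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

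The groups, contrasts, regions, filters, the tools and their alternatives, and the rule for naming positions were fixed before the data were examined. The rule names, per tested contrast, up to 10 higher and up to 10 lower positions past the threshold by absolute log2 change among those whose libraries of one group all lie beyond those of the other. It also names every bulge and loop position, and in comparisons of single libraries the 10 largest NAI differences. Chosen after the data were seen were the restriction to the 5' UTR or to positions before 75, the pooling of NAI and unmodified libraries, the average of the induction changes of NAI and unmodified libraries, the construct difference of the pooled change, the move of the in vitro tables by 51 nucleotides, the in vitro duplicates and the removal of libraries with more than 40% of ends from position 85 on. The pooled and restricted fits were tried after the planned fits had passed 0 positions, and their adjusted p values do not account for that choice.

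The fits were tested on simulated counts, with changes placed only on induction in unmodified libraries. All positions of a fit were given the same spread, estimated per construct. Over all positions edgeR recovered 5.06% of 4-fold and 0 of the 2-fold changes in PP7-wt, and 14.8% and 0.127% in PP7-USs. In the 5' UTR it recovered 97.0% of 4-fold and 61.8% of 2-fold changes in PP7-wt, and 98.3% and 55.0% in PP7-USs, with 2.30% to 3.74% of calls false. Over all positions the few calls at 2-fold were mostly false, 100% of them in PP7-wt and 75.0% in PP7-USs. Libraries of one group differed by more than counting error, with a chi-square per degree of freedom of 9.52 to 109, so counting intervals understate the spread. Read counts per in vivo library ran from 9040 to 101279.

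Alternatives were the library total and edgeR's TMM in place of the reads that reached a position, DESeq2 1.42.0 with its size factors (which also replaces that offset), no count minimum, a mean of at least 50 ends, fits of only the groups compared, a replicate block, and leaving out each library in turn. The labels share only number 1 between groups, so the block sets number 1 against the rest. Deviations of libraries with the same number had a median correlation of -0.10 in PP7-wt and -0.15 in PP7-USs in the 5' UTR, with single values up to 0.0632 and 0.418, but over all positions the medians were 0.249 and 0.113, with single values up to 0.711 and 0.866. The labels do not state a pairing, so the numbers were not taken as pairs in the primary fits, and the block shows what changes if they are. Each in vitro and 5S group has 1 column, so its lanes could not be analysed apart. For single libraries the share of all ends was used in place of the stop rate.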

Results

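SHAPE-seq reads the flexibility of an RNA nucleotide by nucleotide. The reagent 2-methylnicotinic acid imidazole (NAI) acylates flexible nucleotides, reverse transcriptase stops at them, and sequencing counts where the cDNAs end. Escherichia coli cells carried a reporter plasmid with a hairpin from phage PP7 in the 5' UTR of mCherry, and a plasmid from which a PP7 coat-protein fusion was made after induction with 250 nM C4-HSL. The PP7-wt hairpin has an upper stem of 4 base pairs and the PP7-USs hairpin has one of 3, with the same loop and the same bulged adenine. Cells, induced or not, were given 30 mM NAI or 5% DMSO for 5 min. RNA from DMSO-treated cells was also modified in vitro, and 5S rRNA was probed in vivo and in vitro. Positions are counted from the start codon of mCherry, whose first base is 1 and whose preceding base is -1. In PP7-wt the hairpin spans -54 to -30, the bulged adenine is -49 and the loop runs from -44 to -39. In PP7-USs the hairpin spans -52 to -30, the bulged adenine is -47 and the loop runs from -43 to -38.

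The labels list 40 samples in 20 groups. The in vivo tables held 2 libraries for each of 8 groups. In PP7-wt, the NAI libraries of induced cells held 89789 and 101279 read ends and the unmodified ones 25057 and 70519. The NAI libraries of non-induced PP7-wt cells held 9040 and 42919 read ends and the unmodified ones 11782 and 37139. In PP7-USs, the NAI libraries of induced cells held 20621 and 84648 read ends and the unmodified ones 26046 and 59736. The NAI libraries of non-induced PP7-USs cells held 43600 and 44883 read ends and the unmodified ones 31977 and 45422. The 8 in vitro libraries of the constructs held 27612 to 134378 read ends, with 1 library per group. The 4 libraries of 5S rRNA held 3576991 to 6327924 read ends, again with 1 per group. The in vivo libraries differed in where cDNAs ended. In 6 of the 16, position 85 and beyond took 42.2% to 76.9% of the ends, and in the other 10 it took 12.8% to 20.0%.

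The NAI effect in cells asks which nucleotides of the transcript react with the reagent. No position of either construct passed the planned test of NAI against no reagent, in induced or in non-induced cells. The power of that test was not simulated, and a simulated test of induction over all positions missed most changes of 4-fold. The bulged adenine of PP7-wt stopped reverse transcriptase at 0.837% ± 0.295 (SD, n = 2) with NAI and 0.965% ± 0.375 (SD, n = 2) without it in non-induced cells. The whole PP7-USs loop stopped it at 3.00% ± 0.121 (SD, n = 2) with NAI and 2.48% ± 0.517 (SD, n = 2) without it in non-induced cells. In induced cells the PP7-wt loop stood at 2.38% ± 0.0609 (SD, n = 2) with NAI and 2.37% ± 0.0881 (SD, n = 2) without it. The PP7-USs loop of induced cells stood at 2.08% ± 0.144 (SD, n = 2) with NAI and 2.32% ± 0.00851 (SD, n = 2) without it.

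Of 215 PP7-wt positions, 0 passed an adjusted p of 0.05 in edgeR with or without induction, and 0 passed in DESeq2. At an unadjusted p under 0.05, edgeR gave 1 position in each state of PP7-wt, -7 without induction and -61 with it. Of 213 PP7-USs positions, 0 passed in edgeR and 0 in DESeq2. At an unadjusted p under 0.05 these were 2 positions without induction, -7 and 6, and 0 with it. Stops at the guanine at -7 were higher with NAI in non-induced cells of both constructs, by a log2 change of 1.39 (SE 0.465) in PP7-wt and 0.83 (SE 0.262) in PP7-USs, and it was picked out after these values were seen. Among the 7 bulge and loop positions, the log2 NAI effect without induction ran from -0.83 at -41 to 0.10 at -40 in PP7-wt, with 6 of 7 lower. In PP7-USs without induction all 7 were higher, from 0.07 at -47 to 0.93 at -39. With induction the PP7-wt bulge and loop ran from -0.87 at -41 to 0.23 at -40, with 4 of 7 higher. The PP7-USs bulge and loop with induction ran from -0.87 at -40 to 0.25 at -38, with 1 of 7 higher. In simulated data with the same spread at all positions, edgeR recovered 5.06% of 4-fold induction changes in PP7-wt and 14.8% in PP7-USs. The NAI contrasts were not simulated and the 5' UTR varied less, so these shares do not give the power of the NAI tests there. The spread came mainly from the 3' part, where the biological coefficient of variation was 92.9% in PP7-wt and 86.4% in PP7-USs from position 85 on, against 15.2% and 17.4% in the 5' UTR.

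Fitted on the 5' UTR alone, a setting chosen after the data were seen, the NAI effect passed at 1 position, -60 in induced PP7-wt cells. The stop rate there was lower with NAI in both libraries, 15.0% ± 1.85 (SD, n = 2) against 27.8% ± 1.64 (SD, n = 2), with a log2 change of -0.89 (SE 0.230, adjusted p 0.0476 in edgeR). The other 3 NAI contrasts gave 0 positions in that fit in edgeR. At an unadjusted p under 0.05 it gave 2 positions in non-induced PP7-wt cells, and in PP7-USs 8 in non-induced and 0 in induced cells.

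The interaction of induction with NAI asks whether making the coat protein changes which nucleotides react, net of stops that need no reagent. No position passed the test, which has less power than that of the NAI effect and was not itself simulated. For induction without the reagent, over all positions, the simulated test missed most 4-fold changes. Fitted on the 5' UTR alone, after the data were seen, 0 of 85 PP7-wt and 0 of 83 PP7-USs positions passed. The smallest adjusted p in edgeR was 0.7575 and 0.7298 there. In edgeR 0 of 215 PP7-wt and 0 of 213 PP7-USs positions passed, with 1 and 2 at an unadjusted p under 0.05, and 0 passed in DESeq2. Those positions, named after their values were seen, were 49 in PP7-wt and -7 and 13 in PP7-USs. The bulge and loop of PP7-wt ran from a log2 interaction of -0.69 at -49 to 0.68 at -43, with 5 of 7 positive. In PP7-USs they ran from -1.29 at -40 to 0.16 at -38, with 6 of 7 negative. The 6 loop positions of PP7-USs had a median interaction of -0.68 and an adjusted p of 0.264 in the one-direction fry test of edgeR, with 5 of 6 negative.

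Induction without the reagent asks whether reverse transcriptase stops differently when the coat protein is made. The changes with the smallest p lay in the 5' UTR. In PP7-wt stops were lower at several hairpin positions and higher on either side of it, and in PP7-USs the clearest changes were rises downstream of the hairpin. In unmodified PP7-wt libraries the adenine at -60, upstream of the hairpin, rose from 7.54% ± 0.646 (SD, n = 2) to 27.8% ± 1.64 (SD, n = 2). The adenine at -38, the first base after the loop, went from 7.18% ± 0.195 (SD, n = 2) to 2.24% ± 0.974 (SD, n = 2). In PP7-USs the thymine at -23, between the hairpin and the start codon, rose from 1.98% ± 0.309 (SD, n = 2) to 6.32% ± 1.57 (SD, n = 2).

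Over all positions, 0 passed in edgeR in either construct, with 11 in PP7-wt and 7 in PP7-USs at an unadjusted p under 0.05. The 11 in PP7-wt were -80, -61, -60, -59, -25, -23 and 49, which were higher, and -49, -39, -38 and -33, which were lower. The 7 in PP7-USs were -69, -27, -26, -25, -23 and -7, which were higher, and -38, which was lower. DESeq2 passed -38 in PP7-wt, at a log2 change of -2.32 (SE 0.566). It passed 3 positions in PP7-USs, where -25 and -23 were higher and -38 was lower. The 7 bulge and loop positions ran from -1.33 at -39 to 0.23 at -44 in PP7-wt and from -1.16 at -38 to 1.02 at -40 in PP7-USs. As sets, 3 of the 88 combinations of region and contrast passed the edgeR fry test for change in either direction, all of them in this contrast. These were the stretch upstream of the hairpin (adjusted p 0.00242, 19 of 31 positions higher) and the 3' arm of the upper stem (adjusted p 0.0223, 3 of 4 lower) in PP7-wt. The third was the loop of PP7-USs (adjusted p 0.0150, 4 of 6 higher), where -40 was higher and -38 lower, though neither passed alone in edgeR. With the library total in place of the reads that reached a position 0 of the 3 remained, and leaving out 1 library gave 1 to 5. For change in a single direction 0 of the 88 passed. Those with an unadjusted p under 0.05 in this contrast were the stretch upstream of the hairpin (p 0.0318) and the 3' arm of the upper stem (p 0.0476) of PP7-wt, by the same rotation test.

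With the fit limited to the 5' UTR, chosen after these counts were known, 11 of 85 PP7-wt positions passed in edgeR. Stops at -61, -60, -59, -25 and -23 were higher and stops at -49, -48, -39, -38, -37 and -33 were lower. In PP7-USs 3 of 83 passed, at -26, -25 and -23, all higher. In each of the passing positions except -37 of PP7-wt, both induced libraries lay on the same side of both non-induced ones.

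The NAI and unmodified libraries were then pooled, 4 induced against 4 non-induced libraries per construct over the 5' UTR, also a choice made after the planned comparisons. At the positions that passed, stops were lower within the hairpin and higher on both flanks in induced cells. In PP7-wt 16 of 85 positions passed in edgeR, 8 lower and 8 higher. With all positions in the same pooled fit only 1 of 215 passed in PP7-wt and 0 of 213 in PP7-USs, with 18 and 17 at an unadjusted p under 0.05. Within the 5' UTR fit, 1 of the 35 splits of a construct's libraries, the real one, gave as many positions. The highest other gave 6 in PP7-wt and 1 in PP7-USs, which does not cover the choice of that fit. When each split could take its highest count over 3 pooled fits, 6 gave as many in either construct, so chance is not excluded. The matching counts of other splits came from the fits that take in coding positions. All 8 lower ones were among the 25 hairpin positions. Of the 8 higher ones, 4 lay upstream of the hairpin and 4 between it and the start codon. In PP7-USs 12 of 83 passed, with 5 lower among the 23 hairpin positions, 2 higher upstream and 5 higher downstream of the hairpin. The labels do not say whether an NAI and an unmodified library came from the same culture, so the 4 libraries of a side may stand for fewer than 4 cultures.

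In PP7-wt the adenine at -38 had the largest fall, from 6.99% ± 0.574 (SD, n = 4) to 2.01% ± 0.642 (SD, n = 4), a log2 change of -1.88 (SE 0.204, adjusted p 6.5e-07 in edgeR). The bulged adenine at -49 went from 0.901% ± 0.285 (SD, n = 4) to 0.313% ± 0.104 (SD, n = 4), a log2 change of -1.72 (SE 0.233, adjusted p 8.0e-06 in edgeR). The last loop base, the guanine at -39, went from 0.851% ± 0.266 (SD, n = 4) to 0.363% ± 0.0347 (SD, n = 4), a log2 change of -1.40. Stops also fell at -33 in the lower stem, and at -36 and -47 in the upper stem, by log2 changes of -1.48, -1.18 and -0.78. The 5 loop positions from -44 to -40 did not pass, with log2 changes from -0.23 to 0.12. Upstream, the adenine at -60 rose from 6.94% ± 0.943 (SD, n = 4) to 21.4% ± 7.55 (SD, n = 4), a log2 change of 1.62 (SE 0.262, adjusted p 4.7e-05 in edgeR). Its neighbours -59 and -61 rose by 1.29 and 0.84, and -67 by 0.51, of which -61 lost the threshold in 7 of 19 alternatives and -67 in 12. Downstream, the thymine at -23 rose from 3.35% ± 0.589 (SD, n = 4) to 8.56% ± 2.31 (SD, n = 4), a log2 change of 1.38, and -22 rose by 0.85. The naming rule kept only positions where all 4 induced libraries lay beyond all 4 non-induced ones. Of the 16 positions that passed, these 12 met it and the rest, such as -48, -37 and -25, did not. Such a separation held for 18 of all 85 positions, and chance gives 2.86%. The median number of reads that reached -38 was 14984, and the lowest was 713.

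In PP7-USs the thymine at -23 had the largest rise, from 2.35% ± 0.526 (SD, n = 4) to 6.34% ± 1.04 (SD, n = 4), a log2 change of 1.42 (SE 0.200, adjusted p 3.8e-10 in edgeR). Its neighbours -25 and -22 rose by 1.03 and 0.97, and -27 and -26 by 0.83 and 0.69. Upstream, -69 rose by 0.75 and -71 by 0.60. The last loop base, the guanine at -38, had the largest fall, from 0.735% ± 0.175 (SD, n = 4) to 0.350% ± 0.0597 (SD, n = 4), a log2 change of -1.08 (SE 0.256, adjusted p 0.00057 in edgeR). The bulged adenine at -47 went from 1.98% ± 0.214 (SD, n = 4) to 1.17% ± 0.300 (SD, n = 4), a log2 change of -0.82. Stops at -46 in the upper stem and -33 in the lower stem fell by log2 changes of -0.80 and -0.68. The 5 loop positions from -43 to -39 did not pass, with log2 changes from -0.58 to 0.38. Of the 12 positions that passed, these 11 were named because all 4 induced libraries lay beyond all 4 non-induced ones. That separation held for 15 of all 83 positions, against 2.86% by chance. The fit of PP7-USs shared its estimate of spread almost wholly between positions, with a median of 498 degrees of freedom against 21 in PP7-wt. Its p values thus reflect little of the spread between libraries at a single position and are not comparable with those of PP7-wt.

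**Figure D1:**
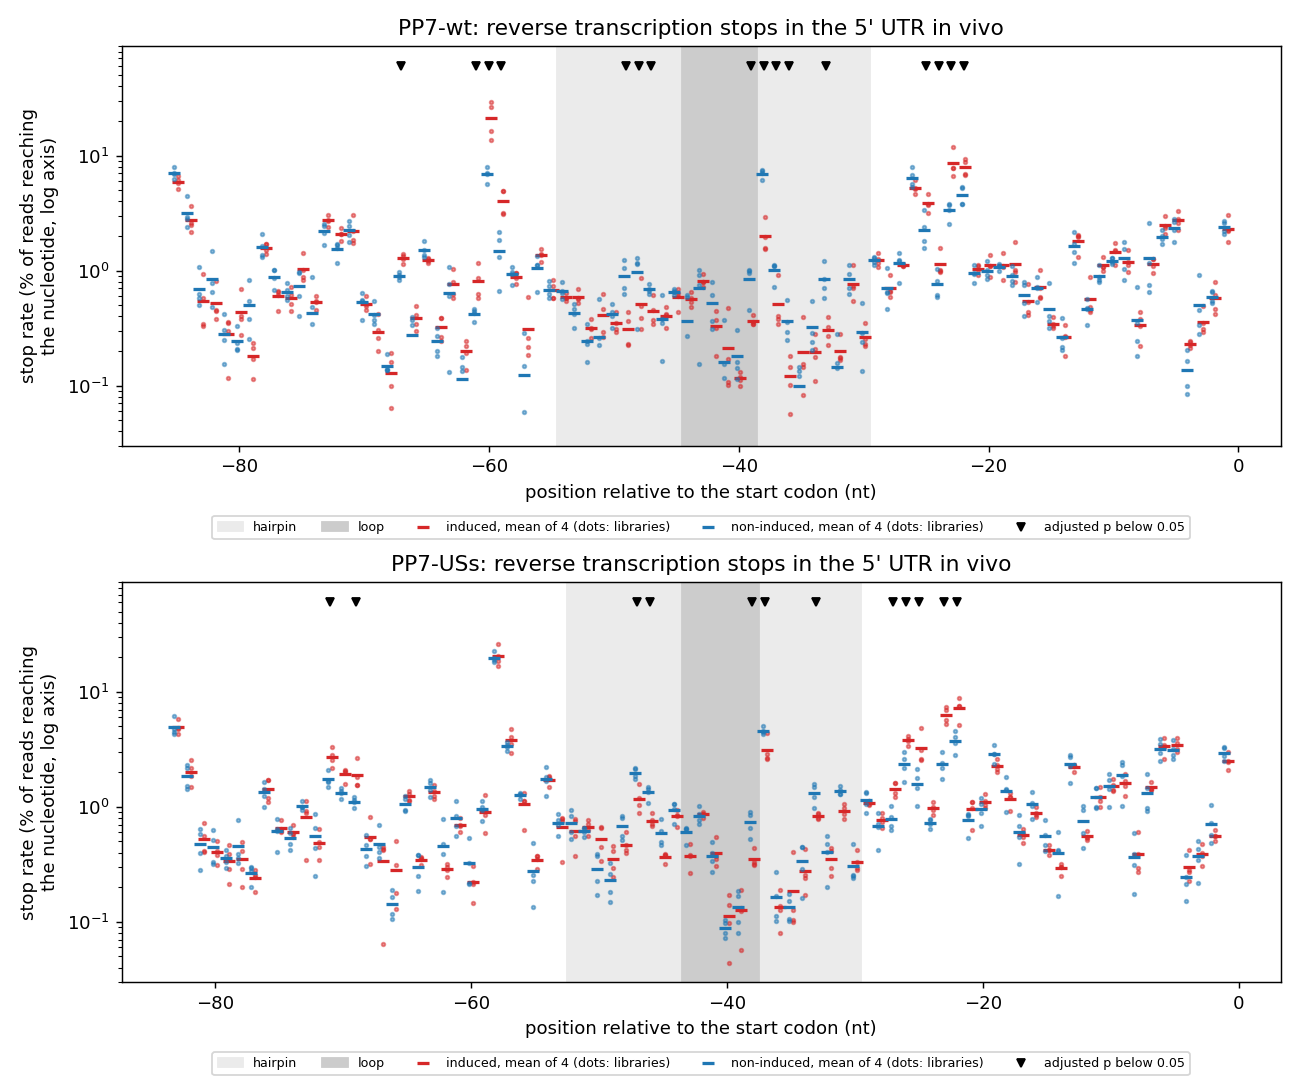
Stop rate at each 5' UTR nucleotide of PP7-wt (top) and PP7-USs (bottom) in vivo, as a percent of the reads that reached it, on a log axis, against the position relative to the start codon. Dots are libraries (those without an end at a nucleotide are not drawn), bars are means of 4 induced (red) or 4 non-induced (blue) libraries, and triangles mark the 16 and 12 positions with an adjusted p under 0.05, all lower on induction inside the hairpin and all higher outside it.

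A similar change appeared in libraries made with and without the reagent at the positions that changed most. Across the 85 PP7-wt positions the induction change in NAI libraries followed that in unmodified libraries with a Pearson r of 0.763 and a Spearman rho of 0.596. Across the 83 PP7-USs positions r was 0.713 and rho 0.660. The sign was the same at 57 of 85 positions in PP7-wt and 48 of 83 in PP7-USs. Each of these 4 values had a permutation p of 1e-05, the smallest that 100000 permutations can give. Positions of an RNA are not independent replicates, so these values describe profiles and not samples. All 16 PP7-wt and all 12 PP7-USs positions changed the same way in the unmodified libraries alone and in the NAI libraries alone, though they had been picked from both together. The NAI libraries alone passed 11 positions in PP7-wt and 5 in PP7-USs in edgeR, next to the 11 and 3 of the unmodified ones. Of those picked from NAI libraries alone, the 7 lower hairpin positions of PP7-wt had a median log2 change of -1.18 in unmodified libraries (fry p 0.0138, 7 of 7 lower). The 3 of PP7-USs, at -47, -46 and -33, had -0.60 (fry p 0.00477, 3 of 3 lower). Without the 3 libraries per construct with more than 40% of their ends from position 85 on, all 16 PP7-wt positions kept direction and threshold. Of the 12 PP7-USs positions 12 kept direction and 7 kept the threshold.

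The comparison of constructs asks whether shortening the upper stem changes the effect of the reagent or of induction. No matched position passed the edgeR test for a difference in the effect of NAI, in fits whose power was not simulated. In edgeR 0 of 213 positions passed for the NAI effect without induction, with induction, or for the interaction, with 0, 2 and 10 at an unadjusted p under 0.05. DESeq2 passed 0, 0 and 24, and the 24 all lay between positions 95 and 131 of the coding region, where the libraries varied most. Fitted on the 5' UTR alone, after the data were seen, 0 of 83 matched positions passed in each of these contrasts. The smallest adjusted p in edgeR was 0.8541, 0.9954 and 0.9659 there. In the loop, the log2 NAI effect without induction was lower in PP7-wt than in PP7-USs at 6 of 6 positions, with a median difference of -0.72 and an adjusted p of 0.0595 in the edgeR fry test. The 5' arm of the lower stem had a median difference of -0.65 and the same adjusted p, with 5 of 5 positions lower. With a replicate block both passed, at an adjusted p of 0.0483. Over the bulge and loop, the difference ran from -1.20 at -41 to -0.16 at -49 without induction and from -0.45 at -49 to 0.52 at -44 with it. For the interaction it ran from -0.28 at -49 to 1.26 at -41.

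For the pooled induction change, 4 of 83 matched 5' UTR positions differed between constructs in edgeR, a comparison added after the data were seen. The match left out -45 and -38 in the longer upper stem of PP7-wt, so its largest fall, at -38, was not compared. The count was 0 with all positions, with positions before 75 or without the libraries with many ends in the 3' part, and 1 to 6 when 1 library was left out. Of 100 assignments of the induction labels, 6 gave as many, so chance is not excluded. The adenine at -60 of PP7-wt, which is -58 in PP7-USs, changed by a log2 of 1.62 in PP7-wt and 0.06 in PP7-USs, a difference of 1.56 (SE 0.329, adjusted p 0.00341 in edgeR). Induced cells were alike there, since PP7-USs stood at 20.6% ± 4.05 (SD, n = 4), and the constructs differed without induction, where PP7-USs stood at 19.8% ± 2.00 (SD, n = 4) against the 6.94% of PP7-wt. The next base, -59 of PP7-wt and -57 of PP7-USs, differed by 1.09 (SE 0.295). Downstream of the hairpin, -27 and -26 rose in PP7-USs by 0.83 and 0.69 and changed by -0.07 and -0.26 in PP7-wt. Their differences were -0.90 (SE 0.254) and -0.95 (SE 0.268). Over the 83 matched positions the constructs' induction changes had a Pearson r of 0.599 (permutation p 1e-05) and a Spearman rho of 0.459 (permutation p 4e-05). Both constructs passed at 8 matched positions, -49, -48, -39, -37, -33, -25, -23 and -22 in the numbering of PP7-wt, each in the same direction in both, where chance gives 1.10.

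In vitro modification asks how the same RNAs react outside the cell. The stop rate was higher in the NAI library than in the unmodified one at most positions of both constructs. Taken at the deposited positions, the stop rate was higher in the NAI library at 84.0% of 194 positions in PP7-wt RNA from induced cells (exact binomial 95% interval 78.1 to 88.9). It was higher at 87.3% of 189 positions in PP7-wt RNA from non-induced cells (81.7 to 91.7). In PP7-USs it was higher at 88.8% of 188 positions (83.4 to 93.0) and at 82.5% of 183 positions (76.2 to 87.7). These intervals treat positions as independent, which positions of an RNA are not. The intervals of the stop rates themselves lay apart, with NAI higher, at 117 of 194 and 113 of 189 positions in PP7-wt and at 119 of 188 and 64 of 183 in PP7-USs. Intervals of stop rates are exact binomial and cover counting error only.

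The in vitro tables do not share a frame with the in vivo ones. In vitro read ends matched in vivo ends when the table was moved by 51 nucleotides towards the 5' end, with a Pearson r across positions of 0.582 in PP7-wt and 0.577 in PP7-USs. Unmoved, r was 0.115 and 0.148, and the next best of the 71 moves tried gave 0.302 and 0.388. Each of the 4 in vitro libraries of either construct had its best match at 51, and the reads of these libraries were 51 nucleotides long. The 5S rRNA tables matched best without a move, at 0.966. Their reads were 51 nucleotides long in both settings, so an offset by the read length would not show in that match.

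**Figure D2:**
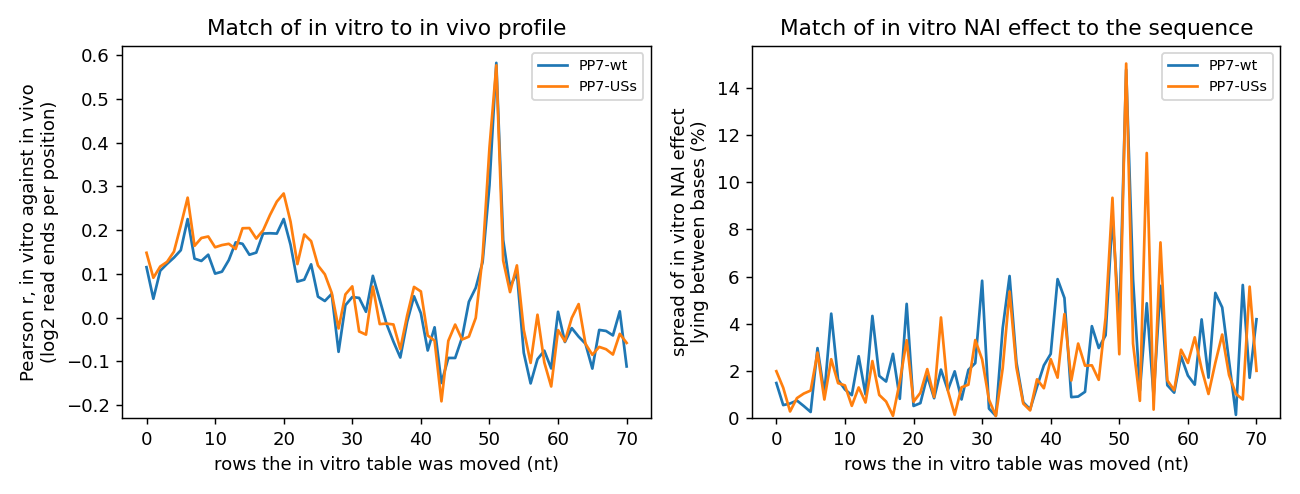
Left, Pearson r between in vitro and in vivo log2 read ends per position against the number of nucleotides the in vitro table was moved, for PP7-wt (blue) and PP7-USs (orange). Right, the percent of the spread of the in vitro NAI effect that lies between the 4 bases, against the same moves; both constructs peak at 51 in both plots.

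By the deposited numbering, the 10 largest NAI differences of PP7-wt RNA from induced cells ranged from 2.13 to 6.01 percentage points, led by -53 in the lower stem (10.9% against 4.90%). In PP7-wt RNA from non-induced cells they ranged from 2.56 to 7.72 points, led by -39 (20.9% against 13.2%). In PP7-USs they ranged from 2.58 to 6.74 points, led by -50, and from 1.82 to 5.64 points, led by -52. The RNAs from induced and non-induced cells shared 3 of the 10 in PP7-wt and 7 of the 10 in PP7-USs. Most of these positions were reached by few reads, as low as 100. In the deposited numbering the loop of PP7-wt holds a position, -40, at which 87.4% of arriving reads ended with NAI and 94.1% without it in RNA from induced cells. In PP7-USs RNA from induced cells 86.3% and 93.1% ended at -38. Both positions are nucleotide 46 of their construct, so these ends follow the nucleotide number and not one loop base. Once moved, nucleotide 46 has no place within the construct. The same holds for the leading positions -53 and -39 of PP7-wt and -50 and -52 of PP7-USs. Their values thus cannot be read as reactivity of stem or loop bases in that frame.

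Moved by 51 nucleotides, the 10 strongest positions of each RNA lay outside the hairpin on both sides, except -52 of PP7-USs at the foot of its stem, and the RNAs from induced and non-induced cells shared 9 of 10 in PP7-wt and 8 of 10 in PP7-USs. In PP7-wt RNA from induced cells the thymine at -58 stopped at 3.66% with NAI (95% interval 3.46 to 3.86) and 1.21% without it (1.10 to 1.32). In PP7-wt RNA from non-induced cells the adenine at -19 led, at 5.52% (5.21 to 5.85) against 2.14% (1.99 to 2.29). In PP7-USs RNA from induced cells -19 led as well, at 5.54% (5.25 to 5.84) against 2.78% (2.65 to 2.92), and in PP7-USs RNA from non-induced cells -56 led, at 3.33% (2.96 to 3.73) against 1.31% (1.10 to 1.55). Over the whole moved loop, PP7-wt RNA from induced cells stopped at 6.89% (6.66 to 7.13) against 3.38% (3.22 to 3.55), and RNA from non-induced cells at 9.83% (9.29 to 10.4) against 8.13% (7.80 to 8.48). The PP7-USs loop stood at 5.87% (5.50 to 6.25) against 3.92% (3.74 to 4.11), and at 5.81% (5.38 to 6.26) against 4.91% (4.54 to 5.30). The bulged adenine of PP7-wt was higher with NAI in RNA from induced cells, at 1.34% (1.23 to 1.46) against 0.394% (0.337 to 0.457). In RNA from non-induced cells its intervals overlapped, at 1.90% (1.64 to 2.20) against 1.58% (1.42 to 1.76). In PP7-USs the bulge overlapped in both RNAs.

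Per the file headers, induction is irrelevant in vitro and both RNAs can serve as duplicates. Treated so, after the data were seen and in the moved frame, 39 of 163 PP7-wt and 76 of 160 PP7-USs positions were higher with NAI in edgeR and none was lower. The adenine at -17 led in both, at 1.14% ± 0.171 (SD, n = 2) against 0.195% ± 0.0306 (SD, n = 2) in PP7-wt and 1.02% ± 0.221 (SD, n = 2) against 0.214% ± 0.00969 (SD, n = 2) in PP7-USs. In the loop, -42, -41 and -40 of PP7-wt passed, with log2 changes of 1.28, 1.47 and 1.22, and so did -43, -41, -40 and -39 of PP7-USs, with 0.77, 1.08, 0.64 and 0.82. The last loop base did not pass in either, at -0.04 in PP7-wt and 0.14 in PP7-USs, and neither did the bulge, at 0.72 and -0.16. At the last loop base of PP7-wt, -39, the 2 RNAs were not alike. Without the reagent it stopped at 0.903% in RNA from induced and 3.93% in RNA from non-induced cells. With NAI it was higher in the former, at 1.41%, and lower in the latter, at 3.31%, with intervals apart in both. Both duplicates with NAI lay above both without it at 98 of 163 and 116 of 160 positions, where chance gives 16.7%. The number of positions that pass moved with the settings. It was 1 in PP7-wt and 46 in PP7-USs with the library total, 1 and 14 with TMM, and 105 and 89 with a block for the RNA source. DESeq2 gave 23 and 7, of which 8 and 2 were lower. Leaving out 1 library brought it to between 2 and 24 in PP7-wt and between 0 and 43 in PP7-USs.

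The 5S rRNA asks how the method behaves on a ribosomal RNA of E. coli, in cells and outside them. The reagent cut the share of full-length cDNA in vivo and in vitro and raised the stop rate at most of the nucleotides with counts, while their shares of all ends fell about as often as they rose. Full-length ends made up 15.4% (95% interval 15.4 to 15.5) with NAI and 32.7% (32.7 to 32.8) without it in vivo, and 4.89% (4.87 to 4.91) against 19.6% (19.6 to 19.7) in vitro. Stop rates were higher with NAI at 86.1% (77.8 to 92.2) of nucleotides in vivo and 90.1% (82.5 to 95.1) in vitro. As shares of all ends only 54.5% and 48.5% of nucleotides were higher with NAI. In vivo the largest differences lay at nucleotides 38, 35, 41, 49, 37, 44, 52, 28, 36 and 51, where NAI raised the stop rate by 2.35 to 6.56 points. At nucleotide 38 it stood at 11.7% (11.7 to 11.8) with NAI and 5.15% (5.12 to 5.18) without it. In vitro they lay at 53, 52, 66, 41, 13, 45, 25, 12, 14 and 35, by 4.66 to 11.6 points. At nucleotide 53 the stop rate was 14.2% (14.2 to 14.3) against 2.67% (2.65 to 2.69), and at 66 it was 9.71% (9.68 to 9.73) against 0.726% (0.718 to 0.735). The lists shared 3 nucleotides, 35, 41 and 52. With 1 library per condition the spread between libraries is unknown.

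**Figure D3:**
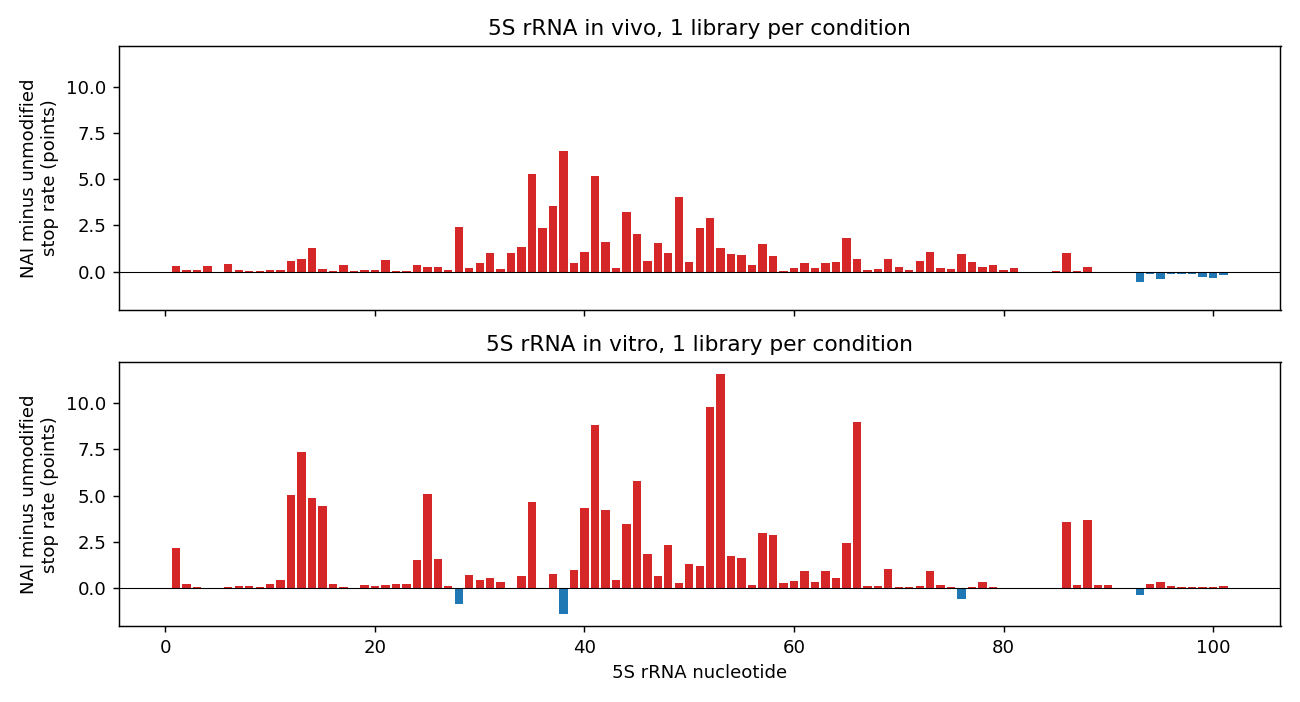
Difference in stop rate between the NAI and the unmodified library, in percentage points, at each 5S rRNA nucleotide in vivo (top) and in vitro (bottom), with 1 library per condition. The largest bar is at nucleotide 38 in vivo and at 53 in vitro; red bars are higher with NAI and blue bars lower.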

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

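The tests of chance, of libraries with many ends in the 3' part and of the reagent were chosen after the results had been seen, and the search for libraries standing apart before, so every explanation here is a hypothesis. The pooled induction change in the 5' UTR differed between constructs at 4 of 83 matched positions, which do not include -38 of PP7-wt. The differences were 1.56 on the log2 scale at -60 of PP7-wt, 1.09 at -59, -0.90 at -27 and -0.95 at -26. Of 100 assignments of the induction labels within constructs, 6 gave as many positions, the real one included, against a highest other of 13, so chance is not excluded for the count. Libraries with many ends in the 3' part, over 40% from position 85 on, are a candidate technical explanation. Without those 6 libraries the difference at -60 was 1.36 (SE 0.525) against 1.56 (SE 0.329) with them, so most of its size stayed. Its adjusted p then rose to 0.184 in edgeR, since the standard error grew with fewer libraries, and it ranged from 7.0e-06 to 0.429 over the alternatives. At -60 induced cells were alike, at 21.4% in PP7-wt and 20.6% in PP7-USs, and non-induced cells were not, at 6.94% and 19.8%. The difference there thus lies in cells in which the coat protein was not induced, and its source was not tested.

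The pooled induction change itself, lower at the passing positions in the hairpin and higher at those around it, was weighed in the same way. For PP7-wt 1 of the 35 splits of its 8 libraries, the real one, gave 16 positions, and the highest other gave 6. For PP7-USs 1 of 35 gave 12, and the highest other gave 1. That is the smallest share 35 splits can give, 2.86%, and it does not cover the choice of the 5' UTR. When each split could take its highest count over the 3 pooled fits (5' UTR, before 75, all positions), 6 of 35 gave as many in each construct, with counts up to 56 and 55, so chance is not excluded. Libraries with many ends in the 3' part could not account for the whole of it, since 16 of 16 positions in PP7-wt and 7 of 12 in PP7-USs kept direction and threshold without them. A reaction with the reagent could not either, since positions picked from NAI libraries alone changed the same way in unmodified libraries alone. In PP7-wt 7 hairpin positions had a median log2 change of -1.18 there (fry p 0.0138) and 4 outside it 1.51 (p 7.4e-05). In PP7-USs 3 hairpin positions had -0.60 (p 0.00477) and 2 outside it 1.31 (p 0.0012). In unmodified libraries alone no position of the PP7-USs hairpin passed in edgeR, and -38 passed in DESeq2. A candidate explanation is coat protein bound to the hairpin in the cell, and how that would change where cDNAs end was not tested. Another is an effect of C4-HSL or of fusion-protein synthesis on transcript ends. The design cannot separate it from binding, because every induced culture had both. In the moved frame, unmodified RNA probed in vitro also stopped less often when it came from induced cells. PP7-wt stood at 0.394% against 1.585% at -49 and 0.903% against 3.93% at -39. PP7-USs stood at 0.748% against 1.77% at -47 and 1.85% against 2.46% at -38. The other loop positions of both constructs were lower as well, though some barely. One was -43 of PP7-wt, at 0.948% against 1.81%, where the pooled change in vivo did not pass. The in vitro difference was thus broader than the in vivo one. Unmodified libraries of both settings came from RNA of induced or non-induced cells. These falls thus cannot tell binding in the cell from the other explanation. With 1 library per group the falls were not tested.

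A library stood apart in 3 of the 66 groups of 4 libraries looked at (named, bulge and loop positions), and chance does so in about 1 of 20. At -39 of PP7-wt the lowest non-induced library was 0.885 of the range away from its neighbour, the NAI library with 9040 ends (0.455% against 0.947% for the nearest). At -38 of PP7-USs an induced NAI library was 0.871 of the range above the others (0.438% against 0.330%). At -43 of PP7-USs a non-induced unmodified library was 0.912 of the range below the others (0.463% against 0.639%). That number is what chance gives, and no explanation was tested.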

How the results depend on the processing

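The alternatives to the pooled, 5' UTR and in vitro duplicate fits were chosen after seeing the data, and the others before. No named in vivo position that passed changed sign under an alternative, and the other passing positions were not followed one by one. The 5S rRNA share higher with NAI in vitro lost its majority when taken from shares of ends, and DESeq2 passed some in vitro positions as lower. Bulge and loop positions that passed neither in the primary fit nor in the alternative were not counted as reversed when their sign changed, a rule set after such changes had been seen. The planned in vivo fits passed 0 positions under the library total, TMM, both filters, the block and each left-out library, and edgeR gave 0 to 11 positions at an unadjusted p under 0.05. DESeq2 passed 1 in PP7-wt and 3 in PP7-USs for induction without NAI, and 24 for the construct difference in the interaction. With 5' UTR positions only, edgeR passed 1 for the NAI effect in induced PP7-wt cells, 11 in PP7-wt and 3 in PP7-USs for induction without NAI, and in NAI libraries alone 11 and 5. With positions before 75, it passed 1 in each construct for induction without NAI. The cause was not tested beyond the lower spread of the 5' UTR.

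The pooled counts, 16 in PP7-wt and 12 in PP7-USs, became 1 and 0 with all positions and 10 and 4 with positions before 75, where the fit takes in the larger spread of the coding region. Of the positions with all positions included, -38 of PP7-wt passed. Without the libraries with many ends in the 3' part PP7-USs gave 7. A replicate block gave 14 and 12, the library total 19 and 15, TMM 18 and 16, and DESeq2 13 and 13. Leaving out 1 library gave 10 to 16 in PP7-wt, lowest without non-induced NAI library 2, and 8 to 22 in PP7-USs, highest without non-induced unmodified library 1. The construct difference, 4, became 0 with all positions, 0 with positions before 75 and 0 without the libraries with many ends in the 3' part, and 1 to 6 when 1 library was left out. It was 1 without induced unmodified library 2 or non-induced NAI library 2 of PP7-wt, or induced NAI library 1 or non-induced unmodified library 2 of PP7-USs. It was 2 without non-induced unmodified library 2 of PP7-wt or induced NAI library 2 of PP7-USs. Of the named positions, 193 of 227 values in PP7-wt, 176 of 209 in PP7-USs and 71 of 104 for the construct difference kept direction and threshold, and the rest kept direction only. Only -38 of PP7-wt passed under all 19 alternatives, and -67 of PP7-wt was lost in 12 and -71 of PP7-USs in 8.

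The region tests for 1 direction, 0 of 88, became 2 with a replicate block, which were the lower stem 5' arm and the loop for the construct difference in the NAI effect without induction, and 0 to 4 when 1 library was left out. The 4 were all loops and came without non-induced NAI library 2 of PP7-wt, which leaves the library of 9040 ends alone in its group. It was 1 without non-induced unmodified library 2 of PP7-wt, non-induced NAI library 1 of PP7-USs or non-induced unmodified library 2 of PP7-USs. The tests for either direction, 3 of 88, became 0 with the library total, 3 with the block and 1 to 5 when 1 library was left out. They were 5 without non-induced NAI library 2 of PP7-wt or non-induced unmodified library 1 of PP7-USs and 1 without non-induced unmodified library 1 of PP7-wt.

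In vitro duplicates, 39 in PP7-wt and 76 in PP7-USs, became 105 in PP7-wt with induced against non-induced RNA as a block (89 in PP7-USs). They became 1 and 46 with the library total, 1 and 14 with TMM, and 23 and 7 with DESeq2, of which 8 and 2 were lower. Leaving out 1 library gave 2 to 24 in PP7-wt, with 11, 2, 4 and 24 without the induced NAI, induced unmodified, non-induced NAI and non-induced unmodified library. In the same order PP7-USs gave 0, 22, 43 and 41. The share of positions higher with NAI, as a share of all ends in place of the stop rate, was lower, at 73.2% and 64.6% in PP7-wt and 69.1% and 71.6% in PP7-USs in vitro, and at 54.5% in vivo and 48.5% in vitro for 5S rRNA. The cause was not tested. Lane-alone alternatives in vitro and for 5S rRNA were not run, as each group has 1 column. Depth limits the left side of the in vitro tables, where as few as 100 reads reached a position.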

Other observations

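The test of whether the match of the in vitro NAI effect to bases peaks at the same move was written down before its result, and the test of altered folding was replaced after its first version had been seen. A candidate explanation of the displacement of the in vitro tables is an offset by the read length. If it were the cause, the NAI effect would follow the base at the moved position. Among 71 moves, 51 ranked 1 in both constructs, with 14.8% of the spread of the NAI effect in PP7-wt and 15.0% in PP7-USs lying between the 4 bases. The next best moves gave 8.56% and 11.2%. At the deposited positions the shares were 1.49% and 1.99%. An RNA folded differently in vitro is another candidate, but its NAI effect should still follow the base at the deposited position. There at most 1.99% of its spread lay between bases. All these shares left out the first 51 deposited nucleotides, and with them most of the hairpin as deposited. The first version of that test asked at which nucleotide the profiles of the constructs stop matching. This was nucleotide 43 in vivo, inside the hairpin at 32 to 56, and nucleotide 73 in vitro, outside both the hairpin and its moved place at 83 to 107, so it decided nothing.

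In the moved frame the median log2 NAI effect in vitro was 0.83 at adenine in PP7-USs and 0.85 in PP7-wt, and 0.76 and 0.85 at thymine. At guanine it was 0.44 and 0.45, and at cytosine 0.22 and 0.37. These are medians over positions of the same RNAs and were not tested.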
